A study of Bos taurus with 10 samples.

How the data were processed

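Liver biopsies of Holstein dairy cows, taken in week 5 of lactation, were profiled on the Affymetrix bovine expression array, on which each transcript is read by 1 or more sets of short probes. Per the labels' protocols, 40 cows were studied, 20 given a control fat and 20 given conjugated linoleic acid (CLA). Both were rumen-protected fats that made up 27.3% of an extra concentrate fed at 630 g of dry matter per cow and day, from week 3 before calving to week 14 after it. RNA of 4 cows was combined into each pool, with 5 pools per group and 1 array per pool, so 10 arrays were used. The sample titles gave each array its group and its pool number.

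The deposited table held log2 expression values, 1 per probe set and array, which the authors had normalized. The submitters' processing notes named Affymetrix Expression Console 1.1 and RMA, a method that corrects background, equalizes the arrays and summarizes the probes of a set. The order and settings of these steps were not given in the sources used here. The values carried 2 decimals and were used as deposited, without further normalization. Of 24128 probe sets in the table, 112 were control probe sets of the manufacturer and 24016 were tested. Probe sets were named through the platform annotation: 13292 had 1 gene symbol, 86 had several and 10638 had none, and no gene was named from a set with several. The gene identifiers of 13263 tested probe sets were found in the RefSeq gene table of assembly ARS-UCD2.0, and 0 symbols differed there. That table was used for names only, and no coordinates are given because the array sources used here named no genome build.

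Differences are CLA minus control on the log2 scale. They were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 on all 10 arrays, without covariates, and adjusted over the 24016 probe sets by the Benjamini-Hochberg method. No filter on dim probe sets was applied in this fit. A lenient count took probe sets with an unadjusted p under 0.05 and a difference of at least 1.3-fold. The chips carry no detection calls in the values used, so signal over background could not be set per gene, and the number of arrays limits the precision.

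Gene lists were tested with camera of limma, with a preset inter-gene correlation of 0.01, on 9155 genes with 1 probe set each, the brightest over the 10 arrays. Camera asks whether the genes of a list differ more than the other genes, so its p does not measure the spread between pools alone. The 21 pathway lists covered lipid, ketone body, carbohydrate and amino acid metabolism, mitochondrial respiration, inflammation, stress responses, the growth hormone axis, coagulation, ribosomes and the cell cycle. Of their 674 symbols 535 were measured. The 11 cell type lists had 114 measured genes, 18 of them also in a pathway list. A list needed 5 measured genes, so 20 pathway lists were tested and ketone body metabolism was described only. Pathway and cell type lists were adjusted separately. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were run beside it. The score of a list in a pool was the mean over its genes of the log2 value minus the mean of the control pools.

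Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took, in each direction, the 10 genes of largest fold past the adjusted test. Places left open went to named genes with an unadjusted p under 0.05 whose CLA and control pools did not overlap. It also took the 4 genes of smallest p in each of the 4 pathway lists of smallest camera p, and the gene of smallest p in every other list. BDH1, BDH2, SLC16A1, CD247, CCL5, PRDX6, MT1A and MT2A are given outside this rule and were not fixed beforehand.

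Array measures were compared with exact two-sided permutation tests over the 252 groupings of the 10 arrays, whose smallest p is 0.0079. The fit was tested on simulated data with the spread of these arrays and 50 changed probe sets per fold size. At a false discovery rate of 5% it recovered 30% of those changed 1.3-fold, 78% at 1.5-fold, 94% at 2-fold and 98% at 3-fold, with 5 unchanged probe sets called. With nothing changed it called 0, and 5.13% of probe sets had an unadjusted p under 0.05. A simulated list with shifted genes was called and 0 unshifted lists were. Probe sets were simulated as independent of each other, so this did not check camera for lists whose genes vary together.

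The alternatives were each pool left out in turn, the pool number as a block, a filter on the dimmest 30% of probe sets, quantile normalization, subtraction of array medians, eBayes with trend and robust options, array weights, an unmoderated test, other fold and discovery thresholds, 1 probe set per gene, and the mean of a gene's probe sets. Cyclic loess normalization, and the fit without the 2 arrays farthest from the rest, were chosen after seeing the data. Milk, blood and liver samples of other weeks were not analysed here.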

Results

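Transcript levels were measured in the liver of dairy cows in week 5 of lactation, 20 of which received a rumen-protected fat with conjugated linoleic acid (CLA) and 20 a control fat. Conjugated linoleic acid is a mixture of linoleic acid isomers with conjugated double bonds. RNA was hybridized as 5 CLA pools and 5 control pools of 4 cows each, so p-values of single probe sets and of list scores measure the spread between pools of 4 cows. Those of camera set the genes of a list against the other genes. The array medians lay between 5.79 and 5.85 on the log2 scale, and the correlation of any pair of arrays, across probe sets, lay between 0.988 and 0.996. The comparison asked which liver transcripts differ with CLA feeding in early lactation.

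Among genes whose CLA pools all lay above the control pools, FXYD2, a regulatory subunit of the sodium-potassium pump, had the largest difference, 1.14 ± 0.23 SE on the log2 scale (2.21-fold). NR3C1, the glucocorticoid receptor, was higher by 0.62 ± 0.12 SE, and its second probe set was higher by 0.23. IRX3, a homeobox transcription factor, was higher by 0.55 ± 0.081 SE, from a low control mean of 4.20. SDHAF4, an assembly factor of succinate dehydrogenase, was higher by 0.52 ± 0.12 SE. The carbonic anhydrase gene CA4 was higher by 0.49 ± 0.093 SE and NRP1, a co-receptor for semaphorins and vascular growth factors, by 0.49 ± 0.11 SE, although NRP1 in control pool 4 lay 0.475 below the mean of the other control pools. SCOC was higher by 0.46 ± 0.11 SE, LMO7 by 0.45 ± 0.12 SE and ACTR10, a dynactin subunit, by 0.44 ± 0.070 SE. For MTR, methionine synthase, the brightest probe set was higher by 0.50 ± 0.14 SE, while its other probe sets differed by 0.05 and -0.09. The second LMO7 probe set differed by 0.10.

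Among genes whose CLA pools all lay below the control pools, MYH10, a nonmuscle myosin heavy chain, differed most, by -0.80 ± 0.17 SE. Its other 3 probe sets differed by -0.12 to -0.15. AK4, a mitochondrial adenylate kinase, was lower (-0.68 ± 0.18 SE), as was CPA1, a carboxypeptidase (-0.56 ± 0.16 SE), a gene near the dim end of the array with a control mean of 3.54 ± 0.36 (SD, n = 5). ZAP70, a kinase of the T cell receptor, differed by -0.44 ± 0.11 SE, and CYP17A1, an enzyme of steroid hormone synthesis, by -0.41 ± 0.10 SE. GPR61 differed by -0.39 ± 0.087 SE, ATF7 by -0.39 ± 0.099 SE, GRK1 by -0.38 ± 0.085 SE and MYNN by -0.35 ± 0.098 SE. GRK1 and MYNN lay among the dimmest 30% of probe sets, with control means of 4.43 and 4.33. The second ATF7 probe set differed by -0.06. CCL3, a chemokine, differed by -0.36 ± 0.089 SE at its brightest probe set, and by -0.05 and 0.05 at its others.

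**Figure D1:**
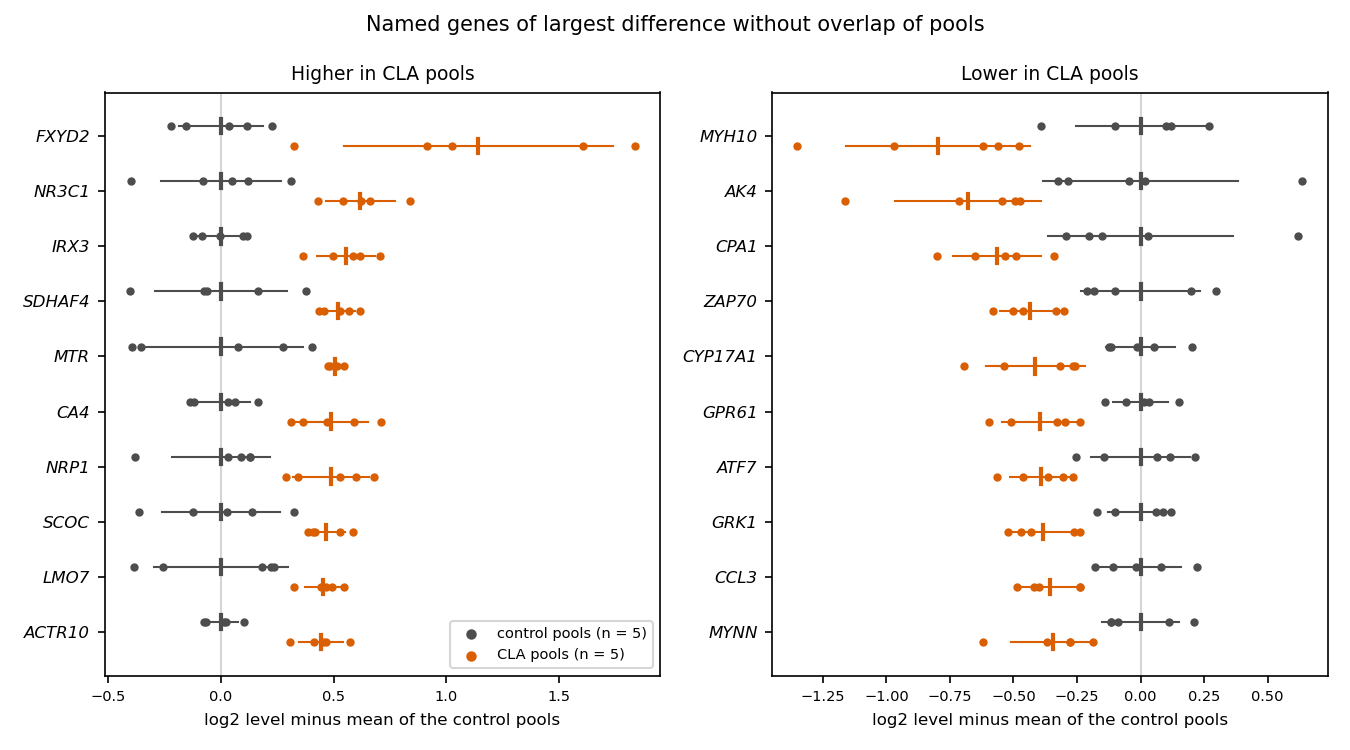
Log2 level of the named genes of largest difference, minus the mean of the control pools, in each pool (points; n = 5 per group), with the mean (tick) and SD (line) of each group. Genes higher in the CLA pools are on the left, led by FXYD2 at 1.14, and genes lower in the CLA pools on the right, led by MYH10 at -0.80. The groups do not overlap for any gene shown, and none passed the adjusted test.

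None of these differences passed the test corrected for all probe sets. In limma with Benjamini-Hochberg adjustment, 0 of 24016 probe sets had an adjusted p under 0.05 and 0 under 0.1, and the lowest was 0.252, that of IRX3 and ACTR10 among others. The unmoderated test also called 0. At an unadjusted p under 0.05 limma counted 2135 probe sets (962 higher and 1173 lower in the CLA pools), where chance alone would give 1200.8, and the unmoderated test counted 2202. The balance between directions depended on the scaling: 1100 were higher and 817 lower after quantile normalization, 1474 and 627 after subtraction of array medians, and 1196 and 779 after cyclic loess normalization. Of the 2135, 216 differed by at least 1.3-fold, 145 higher and 71 lower, and 185 of these stayed under 1.5-fold. That split was 145 to 38 after quantile normalization, 218 to 38 after subtraction of array medians and 156 to 35 after cyclic loess normalization, and without control pool 3 the count was 341. The groups did not overlap for 473 probe sets (283 higher and 190 lower), 1.97% of those tested, against an average of 0.794% by chance. That count was not set against other groupings of the arrays or repeated after another normalization. The array medians themselves did not overlap between the groups (5.79 to 5.82 in the CLA pools, 5.83 to 5.85 in the control pools).

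Of 30 measured genes of fatty acid oxidation and PPARA targets, 24 were higher and 6 lower, with a median difference of 0.069. The difference of the list score was smaller than the spread between pools (0.057 ± 0.079 SE, exact permutation p = 0.548), and stood at -0.0045 without CLA pool 2, 0.026 without control pool 5 and 0.098 without CLA pool 5. ACAA2, the last thiolase of mitochondrial fatty acid oxidation, was higher by 0.20 ± 0.076 SE, ETFB, an electron carrier subunit, by 0.19 ± 0.074 SE, and ACADM, the medium-chain acyl-CoA dehydrogenase, by 0.14 ± 0.061 SE. HADHA, the alpha subunit of the mitochondrial trifunctional protein, differed the other way (-0.22 ± 0.12 SE). Limma's camera gave the list a Benjamini-Hochberg adjusted p = 0.0490, and the adjusted p = 0.964 with an estimated correlation. The call ended without control pools 2 or 5 or CLA pools 1, 2 or 3 (adjusted p from 0.0624 to 0.282), after quantile normalization (median 0.034, adjusted p = 0.719) and after cyclic loess normalization (median 0.032, adjusted p = 0.622). It also ended after subtraction of array medians (adjusted p = 0.0791), without the dimmest 30% of probe sets (0.109), with array weights (median 0.018, adjusted p = 0.219) and without CLA pool 2 and control pool 4, the arrays farthest from the rest (median 0.016, adjusted p = 0.238). The median was 0.013 without CLA pool 2, 0.045 without control pool 5 and 0.11 without CLA pool 5. Over the 10 pools, with group means removed, the score of this list followed the spread of values on the array. Pearson's r was 0.925 (permutation p = 0.00049, Benjamini-Hochberg adjusted 0.00196 over 4 relations) and Spearman's rho 0.879 (permutation p = 0.00265), and r was 0.954 without the 2 pools farthest from the median spread. The genes of the list are bright (mean log2 signal 10.02), and higher values of bright genes go with a wider array, so part of this relation was built in. Other bright lists were not tested against array spread, so the relation is not shown to be particular to fatty acid oxidation.

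Of 4 measured genes of ketone body metabolism, ACAT1 and BDH1, which act in ketone body synthesis and use, passed when limma's p was adjusted over the list alone, and 0 passed over all genes tested. ACAT1 was higher by 0.26 ± 0.081 SE (Benjamini-Hochberg adjusted p = 0.0333 over the list alone). BDH1 was higher by 0.27 ± 0.10 SE (adjusted p = 0.0466 in the same way), while BDH2 differed by 0.03 ± 0.16 SE and SLC16A1 by -0.03 ± 0.16 SE. ACAT1 no longer passed without control pools 1, 2 or 4 or CLA pools 2 or 3 (adjusted p from 0.0541 to 0.0928), nor BDH1 without these pools or CLA pool 5 (0.0634 to 0.124). In the oxidative phosphorylation list 35 of 54 genes were higher, with a median of 0.026. It turned negative after quantile and cyclic loess normalization and in some fits with a single pool left out. SDHD was higher by 0.21 ± 0.072 SE, NDUFB5 by 0.21 ± 0.097 SE, ATP5F1B by 0.19 ± 0.086 SE and UQCRC2 by 0.17 ± 0.083 SE, but the second probe sets of ATP5F1B and UQCRC2 differed by -0.15 and -0.14. In the list of the urea cycle and amino acid catabolism 19 of 29 genes were higher (median 0.060, 0.034 without control pool 2 and 0.014 without control pool 5). BHMT, which remethylates homocysteine from betaine, was higher by 0.51 ± 0.18 SE at its brightest probe set and differed by -0.18 at the other. GOT1 and GPT2, both aminotransferases, were higher by 0.32 ± 0.12 SE and 0.28 ± 0.11 SE, and BCKDHB by 0.15 ± 0.079 SE. Both lists missed the threshold of camera (Benjamini-Hochberg adjusted p = 0.162 each). Without control pool 4 both passed, oxidative phosphorylation at a median of 0.044 (adjusted p = 0.00811) and the urea cycle list at 0.079 (adjusted p = 0.0124), and oxidative phosphorylation passed without CLA pool 5 (median 0.081, adjusted p = 7.37e-05).

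Of 29 measured genes of the cell cycle, 22 were lower and 7 higher, with a median difference of -0.13. The list score differed by -0.117 ± 0.099 SE (exact permutation p = 0.278). CLA pool 2 had the highest score of the 10 pools, 0.193, and the difference was -0.194 without it, -0.074 without control pool 2 and -0.071 without CLA pool 4. NUSAP1, a spindle protein, differed by -0.38 ± 0.14 SE, and the mitotic kinase AURKA by -0.22 ± 0.083 SE. MCM3, part of the replicative helicase, differed by -0.24 ± 0.11 SE and CENPF, a kinetochore protein, by -0.25 ± 0.12 SE. The second probe sets of AURKA and MCM3 differed by 0.01 and 0.03, and that of CENPF by -0.14. Camera gave the list a Benjamini-Hochberg adjusted p = 0.0236, and the adjusted p = 0.964 with an estimated correlation. The call ended without control pools 2 or 5 or CLA pools 1 or 4 (adjusted p from 0.0862 to 0.315; median -0.080 without control pool 2 and -0.070 without CLA pool 4), after quantile normalization (adjusted p = 0.125) and after cyclic loess normalization (adjusted p = 0.136).

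Of 13 markers of T and NK lymphocytes, 11 were lower and 2 higher, with a median of -0.16. Their score differed by -0.138 ± 0.089 SE (exact permutation p = 0.175), and by -0.087 without control pool 1. CD2 differed by -0.33 ± 0.16 SE at its brightest probe set and by -0.05 and -0.03 at its others, CD247 by -0.20 ± 0.097 SE and CCL5 by -0.23 ± 0.15 SE. Camera gave a Benjamini-Hochberg adjusted p = 0.0378, and the adjusted p = 0.911 with an estimated correlation. The call ended without control pools 1 or 2 or CLA pools 1 or 5 (adjusted p from 0.106 to 0.354; median -0.090 without control pool 1), after quantile normalization (adjusted p = 0.134), after cyclic loess normalization (adjusted p = 0.169), with array weights (adjusted p = 0.0877) and with the mean of a gene's probe sets (adjusted p = 0.116).

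**Figure D2:**
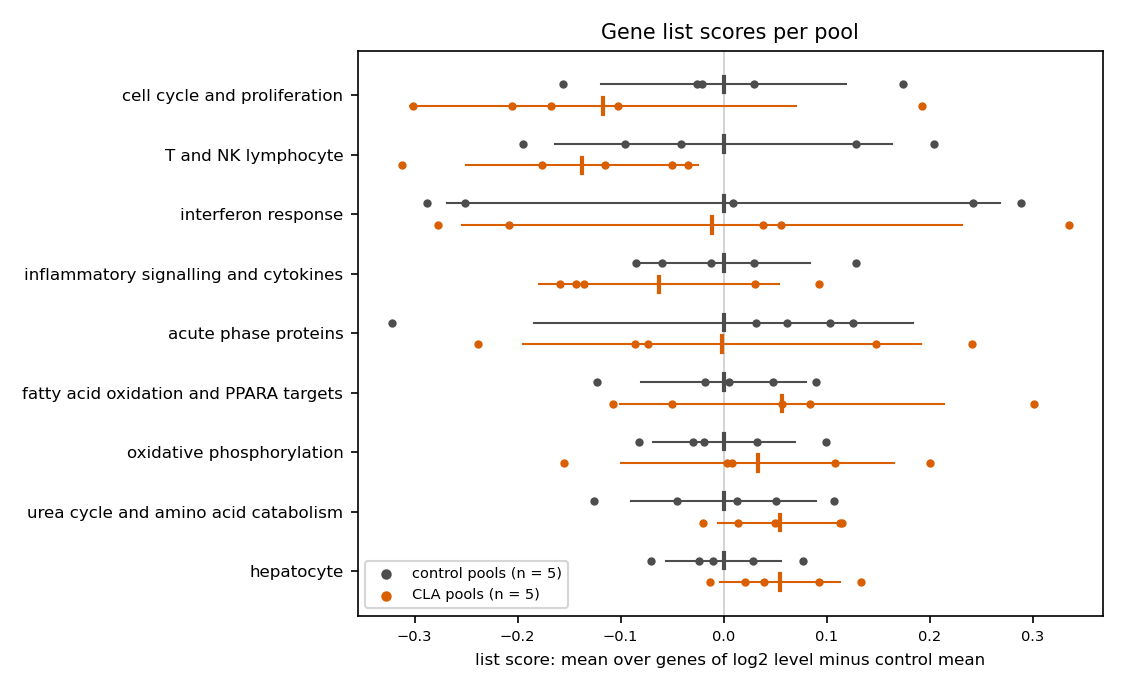
Scores of 9 gene lists per pool, each the mean over the list's genes of the log2 level minus the control mean (points; n = 5 pools per group), with group mean (tick) and SD (line). The cell cycle score of the CLA pools lies around -0.12 and that of the T and NK lymphocyte list around -0.14, with overlap between the groups in both. For fatty acid oxidation CLA pool 2 lies highest, at 0.301. The mean difference is smaller than the SD of the pools in both groups for every list shown except T and NK lymphocytes. There it is -0.138, against an SD of 0.163 in the control and 0.113 in the CLA pools. The median of the oxidative phosphorylation and acute phase lists turns sign after quantile and cyclic loess normalization.

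The remaining metabolic lists missed the threshold of camera (Benjamini-Hochberg adjusted p of 0.195 or more). In lipogenesis and fatty acid desaturation 13 of 23 genes were higher, with a median of 0.020 that turned negative after quantile and cyclic loess normalization. INSIG1, an inhibitor of lipid synthesis, was higher by 0.35 ± 0.16 SE. Cholesterol synthesis and uptake had 8 genes higher and 8 lower of 17, with a median of 0.00, and INSIG2 was higher by 0.32 ± 0.13 SE. In carnitine synthesis and uptake 7 of 8 genes were higher (median 0.077), among them BBOX1, the last enzyme of carnitine synthesis (0.20 ± 0.10 SE). CYP7A1, the rate-limiting enzyme of bile acid synthesis, was higher by 0.46 ± 0.14 SE, while its list had 6 genes higher and 6 lower, with a median of 0.014 that turned negative after quantile normalization. Lipoproteins and lipid export had 11 of 17 genes higher (median 0.048), with APOH at 0.11 ± 0.061 SE. Gluconeogenesis and glycolysis had 10 higher and 13 lower (median -0.010, positive after subtraction of array medians), and PYGL, liver glycogen phosphorylase, was higher by 0.27 ± 0.087 SE at its brightest probe set and by 0.02 at the other. In the somatotropic axis 11 of 16 genes were higher (median 0.047, 0.015 without control pool 2 and 0.083 without CLA pool 2), and the insulin receptor INSR differed by -0.37 ± 0.18 SE, with its other probe sets between 0.00 and -0.30. In xenobiotic and steroid metabolism 14 of 25 genes were higher (median 0.030). Without control pool 4 the list passed (median 0.055, adjusted p = 0.0139), and its median lay between 0.0095 and 0.016 without control pools 1, 2 or 5 or CLA pools 1 or 2. FMO5, a flavin monooxygenase, was higher by 0.31 ± 0.071 SE at its brightest probe set and was the 1 member to pass limma's test with Benjamini-Hochberg adjustment, adjusted over the list alone (adjusted p = 0.0237), with 0 over all genes tested. It did so without control pools 2 or 3 or CLA pool 1, but not without any other single pool (adjusted p from 0.0525 to 0.0777). Its 4 other probe sets differed by -0.14 to 0.03.

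Lists of inflammation, stress and protein synthesis did not pass camera either (Benjamini-Hochberg adjusted p from 0.195 to 0.964). Of 32 genes of inflammatory signalling and cytokines 20 were lower and 11 higher (median -0.049), with CCL3 leading. That list passed without CLA pool 4 (median -0.065, adjusted p = 0.0294), and its median was -0.017 without control pool 2, -0.0078 without CLA pool 5, -0.083 without control pool 5 and -0.077 without CLA pool 2. In the acute phase list 12 genes were higher and 11 lower, with a median of 0.020 that turned negative after quantile and cyclic loess normalization, and APCS, serum amyloid P, differed by -0.31 ± 0.13 SE. Complement and coagulation had 24 of 41 genes higher, with a median of 0.018 that turned negative under the same normalizations. The list passed without CLA pool 2 (median 0.032, adjusted p = 0.0264), and F13B was higher by 0.17 ± 0.081 SE. In the interferon response 16 of 26 were lower (median -0.014, positive after subtraction of array medians), with PSMB8, an immunoproteasome subunit, at -0.31 ± 0.14 SE. The list of NRF2 targets and glutathione had 16 higher and 15 lower (median 0.002). Within it the antioxidant enzymes GPX2 and PRDX6 were higher by 0.37 ± 0.10 SE and 0.23 ± 0.078 SE, and the metallothioneins MT1A and MT2A, which bind zinc and copper, differed by -1.19 ± 0.50 SE and -0.76 ± 0.27 SE. Of 24 genes of the endoplasmic reticulum stress response 15 were lower (median -0.028), with DDIT3 at -0.14 ± 0.081 SE. Cytosolic ribosomal proteins had a median of 0.002 over 53 genes, with RPL7 at 0.11 ± 0.067 SE and its second probe set at -0.08. In the list of sampling stress, early response and heat shock 14 of 28 were lower (median -0.008, positive after subtraction of array medians), and FOSB differed by -0.32 ± 0.085 SE, with its second probe set at -0.15.

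The other cell type lists did not pass camera (Benjamini-Hochberg adjusted p of 0.437 or more). Hepatocyte markers were higher in 9 of 12 (median 0.035), with FGB at 0.21 ± 0.14 SE. Kupffer cell and macrophage markers were lower in 9 of 11 (median -0.050), with CD68 at -0.23 ± 0.14 SE, and B lymphocyte and plasma cell markers in 5 of 7 (median -0.042), with BLK at -0.37 ± 0.15 SE. Erythroid markers were lower in 7 of 8 (median -0.058), with HBA at -0.24 ± 0.076 SE, and skeletal muscle markers in 8 of 11 (median -0.044), although MYH7 was higher by 0.17 ± 0.094 SE at its brightest probe set and lower at its others (-0.13 and -0.27). Endothelial markers were lower in 8 of 12 (median -0.049), while EMCN was higher by 0.25 ± 0.088 SE at its brightest probe set and differed by -0.01 at the other. Stellate cell and fibroblast markers were higher in 9 of 14 (median 0.034), with LRAT at 0.22 ± 0.087 SE, and passed without CLA pool 2 (median 0.099, adjusted p = 0.0200). The cholangiocyte median was -0.054, with KRT19 at 0.19 ± 0.13 SE. The neutrophil median of -0.010 turned positive after subtraction of array medians and cyclic loess normalization, with CATHL4 at -0.17 ± 0.071 SE. The adipocyte median of -0.016 turned positive under all 3 normalizations, with PPARG at -0.16 ± 0.077 SE. HBA, CATHL4 and PPARG lay near the dim end of the array, with control means of 4.03, 3.65 and 3.53. Median, mean and test of a list differed in sign for gluconeogenesis, acute phase, NRF2, sampling stress, cholangiocyte and adipocyte genes. Over the pathway and cell type lists other than ketone body and xenobiotic metabolism, 0 members passed adjusted over the list alone, and 0 passed over all genes tested.

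The values of the CLA arrays were spread more widely than those of the control arrays. The array SD was 2.40 ± 0.018 (SD, n = 5) against 2.37 ± 0.017 (exact permutation p = 0.0238), and the array median was 5.81 ± 0.012 against 5.84 ± 0.011 (SD, n = 5; exact permutation p = 0.0079, the smallest the design allows). Adjusted over 8 array measures by the Benjamini-Hochberg method, both gave 0.0635. The median difference of a probe set ran from -0.048 in the dimmest to 0.028 in the brightest of 10 equal groups of probe sets by signal. The bacterial hybridization controls averaged 11.30 ± 0.14 in the CLA and 11.38 ± 0.19 in the control arrays (SD, n = 5; exact permutation p = 0.571). The 3' minus 5' difference of 6 control transcripts, a sign of RNA integrity, was 2.53 ± 0.31 and 2.52 ± 0.31 (SD, n = 5; exact permutation p = 0.944).

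**Figure D3:**
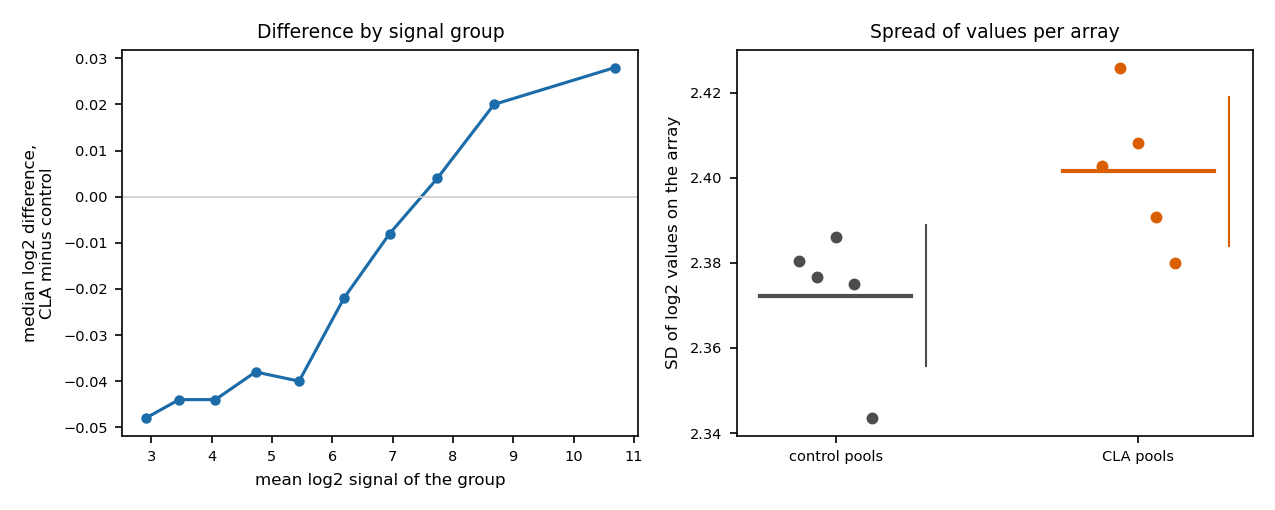
Left, median log2 difference (CLA minus control) of the probe sets in 10 equal groups by mean log2 signal, against the mean signal of each group. It runs from -0.048 to 0.028. Right, SD of the log2 values on each array (points; n = 5 per group) with group mean (horizontal line) and SD (vertical line), 2.40 in the CLA pools and 2.37 in the control pools.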

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

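The splits for the counts at a false discovery rate of 5% and at an unadjusted p under 0.05 and for single lists, the count of probe sets lower in both of 2 pools, the test of the hybridization controls, and cyclic loess normalization were chosen after the result was seen. The SD margin applied to the 3' minus 5' difference of CLA pool 2 was not in the criterion written beforehand.

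The first pattern is how many probe sets and lists differed, set against 100 splits of the 10 arrays into 5 and 5, the real one included. Chance cannot be excluded for the 216 probe sets of at least 1.3-fold, since 32 splits gave as many (highest other 591), for the 2 pathway lists (93 splits, highest other 13) or for the 1 cell type list (76 splits, highest other 7), while the 0 probe sets at a false discovery rate of 5% (highest other 1) leave nothing to test, as any split gives at least 0. The other splits had medians of 168 probe sets and 5 pathway lists, so groupings that ignore the diet often gave as many lists. Whether a structure among the arrays lay behind the highest counts was not tested. For the 2135 probe sets with an unadjusted p under 0.05, 4 splits gave as many (highest other 2400). After cyclic loess normalization 4 did so too (1975, highest other 2228). After quantile normalization 5 splits reached the count of 1917 (highest other 2393). The first 2 lie just under 5% of the splits, were chosen after the result was seen, and were not corrected for the other checks. Chance is therefore not clearly excluded, and an effect of the diet stays open.

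The second pattern is the 3 lists past camera, for none of which chance can be excluded: 28 of the 100 splits gave the cell cycle list a camera p as small (on the -log10 scale 2.93, highest other 13.04), 28 that of fatty acid oxidation (2.31, highest other 8.18) and 23 that of T and NK lymphocytes (2.46, highest other 6.76). Among 10000 random lists matched on signal, the median of the cell cycle list lay at percentile 0.03, that of the T and NK list at 0.15 and that of fatty acid oxidation at 99.54, but random genes vary independently, while the calls ended with an estimated correlation (adjusted p = 0.964, 0.911 and 0.964). That bound was therefore too narrow, and a trend with signal level cannot be told apart from other causes: the score differences lay within 2 SE of 0 before any correction, too few pools for their change after quantile normalization to decide (cell cycle -0.117 ± 0.099 SE to -0.098 ± 0.0996, T and NK -0.138 ± 0.089 to -0.122 ± 0.084, fatty acid oxidation 0.057 ± 0.079 to 0.030 ± 0.069; n = 10 pools). For fatty acid oxidation, array spread is a candidate explanation: the CLA coefficient of its score was -0.14 ± 0.044 SE with array spread in the fit, so no positive difference was left, though spread differed between the groups and the fit then predicts more (0.197) than was observed. The genes of this list are bright, so its score and array spread are not independent measures. Whether a differing share of T and NK lymphocytes lay behind the cell cycle list cannot be told apart from other causes either, because the scores correlated at r = 0.330 within groups (permutation p = 0.337), too few pools to decide, and an effect of CLA feeding on these lists stays open.

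The third pattern is probe sets standing apart by at least 2-fold in a single pool, 128 in control pool 4 and 37 in control pool 5, all of them lower, and 160 in CLA pool 2, of which 135 were lower. Loss of the whole transcript could be checked only for the 130 lower probe sets of any pool with another probe set of the same gene. Their median gap was -1.31 and that of the other probe sets -0.12, which argues against such a loss for most of the 130. For 12 the others were at least 2-fold lower too. The 130 were picked for a large gap, so part of that contrast was set by the choice, and nothing was tested for the rest. A loss shared by CLA pool 2 and control pool 5 is a candidate explanation for part of them. Of the 37, 9 were also among the 135 (0.208 by chance), and the 37 had a median of -0.75 in CLA pool 2. Of the 135, 21 were at least 2-fold lower in control pool 5, against 0 to 3 in each other control pool. For the 135 as a whole a shared loss cannot be told apart from other causes, as 74 were lower in control pool 5 and the median there was -0.043, over members going both ways. The 128 of control pool 4 shared 1 with CLA pool 2 (0.72 by chance), with medians of -0.23 there and -0.51 in CLA pool 5. RNA degradation or weaker hybridization of CLA pool 2 cannot be told apart from array-to-array variation. Its mean 3' minus 5' difference of 2.97 passed the highest other array, control pool 5 (2.93), by less than the SD of the others (0.258). The criterion for degradation written beforehand, a value above all other arrays, was therefore met, though narrowly. The margin of the SD was not part of that criterion. The hybridization controls of CLA pool 2, at 11.09, lay under the lowest other (11.22) by less than the SD of the others (0.146). Single control transcripts went both ways. The ef1a difference was 3.47 in CLA pool 2 and 2.09 in control pool 5, against -0.09 to 0.88 elsewhere. That of eIF-4E was also highest in CLA pool 2 (5.99), while those of actin, gapd, Cyph and GST lay within the range of the other arrays. No biological explanation was tested, since the labels give nothing that sets single pools apart.

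Single pools also stood apart from the other 4 of their group, by Dixon's test at the 95% level, in 16 of 218 checks, where chance would give 10.9. Each value is the pool's distance from the mean of the other 4 pools. In CLA pool 2 the somatotropic score was lower (-0.255) and the scores of ribosomal proteins (0.193) and sampling stress (0.362) higher, and the 3' minus 5' difference of ef1a was higher by 3.02. In control pool 4 the acute phase score (-0.403) and NRP1 (-0.475) were lower and the xenobiotic (0.185) and endothelial (0.335) scores higher. In control pool 5 the gluconeogenesis score (-0.203) and the array SD (-0.0360) were lower and the hybridization controls higher (0.408). In CLA pool 5 SDHD was lower (-0.0925) and the 3' minus 5' difference of gapd higher (0.4525). The cholesterol score was higher in CLA pool 3 (0.109), the xenobiotic score in CLA pool 1 (0.0675) and the skeletal muscle score in control pool 1 (0.305).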

How the results depend on the processing

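Cyclic loess normalization and the fit without CLA pool 2 and control pool 4, the arrays farthest from the rest, were chosen after seeing the data. The count of probe sets at a false discovery rate of 5% in limma stayed at 0 under all other settings tried, with 1499 to 2297 probe sets at an unadjusted p under 0.05. The 20 genes of largest difference named for groups without overlap had an unadjusted p under 0.05 in all 357 values over 18 settings. The direction of these 20 held, as did that of the other genes named by the rule. The 20 were picked from these same arrays for that p and for groups without overlap, so this was largely set in advance. CPA1, GRK1 and MYNN had no value after the filter on the dimmest 30% of probe sets. Of 1128 values of the genes named by the rule, 981 stayed on their side of an unadjusted p of 0.05, 73 came to lie under it and 74 above it. The medians of the 3 lists past camera kept their direction under every setting tried, but the lists did not keep their call, and the fatty acid oxidation score turned to -0.0045 without CLA pool 2. Signal over background was not available, and dim genes such as CPA1, PPARG, CATHL4, HBA, MYNN and GRK1 carry the least signal. Except where fewer arrays or probe sets entered a fit, the cause was not tested.

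With the replicate number as a block, 1 pathway list passed, fatty acid oxidation keeping its median of 0.069 with an adjusted p of 0.0591. No pairing of the pools by number was visible in the values. The deviations of same-numbered pools correlated between -0.0855 and 0.0925, 0 pairs lay above 0.1 and 0 of 5 CLA pools were closest to their own number. Which cows went into which pool is not given, so a pairing by design cannot be excluded. No other call on a count or a list that had passed was changed by the block, which gave 234 probe sets of at least 1.3-fold.

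After quantile normalization 38 probe sets of at least 1.3-fold were lower, and 0 pathway and 0 cell type lists passed, with medians of 0.034 for fatty acid oxidation, -0.11 for the cell cycle and -0.13 for T and NK lymphocytes. Signs turned for lipogenesis (-0.016), bile acids (-0.0076), acute phase (-0.021), complement and coagulation (-0.015), oxidative phosphorylation (-0.013) and adipocyte markers (0.029). After cyclic loess normalization 35 were lower and 0 lists of either kind passed, with medians of 0.032, -0.11 and -0.13 for the same lists. Signs turned for lipogenesis (-0.012), acute phase (-0.023), complement and coagulation (-0.024), oxidative phosphorylation (-0.011), neutrophil (0.013) and adipocyte markers (0.029). With array medians subtracted 218 were higher and 38 lower, and 1 pathway list passed, fatty acid oxidation missing it with a median of 0.10. Signs turned for gluconeogenesis (0.021), interferon (0.017), sampling stress (0.023), neutrophil (0.021) and adipocyte markers (0.015).

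With array weights 1 pathway and 0 cell type lists passed, with medians of 0.018 for fatty acid oxidation and -0.16 for T and NK lymphocytes, and signs turned for lipoproteins (-0.021) and adipocyte markers (0.0089). Without the dimmest 30% of probe sets 1 pathway list passed, fatty acid oxidation missing it at a median of 0.069, and signs turned for neutrophil (0.0080), cholangiocyte (0.016) and adipocyte markers (0.018). With an estimated correlation, and with fry, 0 pathway and 0 cell type lists passed, with medians as before (0.069, -0.13 and -0.16). With the mean of a gene's probe sets 0 cell type lists passed, T and NK lymphocytes at -0.13, and complement and coagulation turned sign (-0.010). Over all settings the adjusted p ran from 0.00352 to 0.985 for fatty acid oxidation, from 2.85e-08 to 0.985 for the cell cycle and from 0.00233 to 0.911 for T and NK lymphocytes.

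Without CLA pool 2 and control pool 4, 1 probe set passed the false discovery rate of 5% in limma, that of CGN1, conglutinin (0.97, Benjamini-Hochberg adjusted p = 0.0302). It differed by 0.58 over all 10 arrays. Of probe sets of at least 1.3-fold 121 were lower, 7 pathway and 2 cell type lists passed, and fatty acid oxidation did not (median 0.016). The lists gained were inflammatory signalling (-0.096), interferon (-0.12), the somatotropic axis (0.083), complement and coagulation (0.065), the urea cycle (0.075), xenobiotic metabolism (0.048) and stellate cell and fibroblast markers (0.14). Signs turned for carnitine (-0.0075) and adipocyte markers (0.045).

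A threshold of 1.5-fold left 31 probe sets (18 higher, 13 lower), 1.2-fold gave 891 (465 and 426), no fold threshold 2135 (962 and 1173), and 1 probe set per gene 87 (59 and 28). With no fold threshold the majority turned to higher after quantile normalization (1100 and 817), with array medians subtracted (1474 and 627) and after cyclic loess normalization (1196 and 779).

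With single pools left out, the count at 1.3-fold ran from 207 to 341 and its lower part from 69 to 128, both highest without control pool 3. Between 0 and 5 pathway lists passed, 0 without control pools 2 or 5 or CLA pool 1 and 5 without control pool 4 (gaining oxidative phosphorylation, the urea cycle and xenobiotic metabolism), and between 0 and 2 cell type lists, 0 without control pools 1 or 2 or CLA pools 1 or 5 and 2 without CLA pool 2. The medians of lists that had passed ran from 0.013 to 0.11 for fatty acid oxidation, from -0.17 to -0.070 for the cell cycle and from -0.21 to -0.090 for T and NK lymphocytes. Lists that changed sign in some of these fits ran from -0.073 to 0.043 (lipogenesis), -0.035 to 0.023 (gluconeogenesis), -0.010 to 0.084 (lipoproteins), -0.023 to 0.041 (bile acids), -0.013 to 0.036 (acute phase), -0.079 to 0.021 (endoplasmic reticulum stress), -0.076 to 0.049 (interferon), -0.0055 to 0.043 (complement and coagulation), -0.016 to 0.081 (oxidative phosphorylation) and -0.059 to 0.047 (sampling stress). Cell type medians did so from -0.11 to 0.022 (Kupffer cell and macrophage), -0.18 to 0.030 (B lymphocyte and plasma cell), -0.079 to 0.043 (neutrophil), -0.063 to 0.0095 (endothelial), -0.017 to 0.10 (stellate cell and fibroblast), -0.10 to 0.033 (skeletal muscle) and -0.058 to 0.025 (adipocyte). Medians also lay on both sides of 0 for NRF2 (-0.041 to 0.035) and ribosomal proteins (-0.042 to 0.023), each 0.002 over all 10 arrays. The same held for cholesterol (-0.044 to 0.029), at 0.00 over all 10 arrays. The remaining medians ran from 0.063 to 0.19 (ketone body), 0.043 to 0.11 (carnitine), -0.083 to -0.0078 (inflammatory signalling), 0.015 to 0.083 (somatotropic), 0.014 to 0.081 (urea cycle), 0.0095 to 0.055 (xenobiotic), 0.025 to 0.061 (hepatocyte), -0.065 to -0.033 (cholangiocyte) and -0.11 to -0.046 (erythroid).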

Other observations

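The genes, families and relations in this part were chosen after their values were seen.

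Besides FXYD2, 4 probe sets with an unadjusted p under 0.05 differed by at least 2-fold, all of them lower in the CLA pools and all with overlapping groups. SLC2A5, a fructose transporter, averaged 5.62 ± 1.08 in the CLA pools and 7.05 ± 0.74 in the control pools (SD, n = 5), a difference of -1.43 ± 0.48 SE (Benjamini-Hochberg adjusted p = 0.428 in limma). Its other probe sets differed by -0.24 and -0.20. The metallothionein MT1A lay between 11.71 and 12.82 in the control pools, and at 9.83, 9.88, 10.93, 12.33 and 12.57 in the CLA pools, so 3 of the 5 lay below every control pool. The other 2 had no gene symbol and differed by -1.09 ± 0.47 SE and -1.39 ± 0.62 SE, and in both, as for MT1A, CLA pools 1, 2 and 3 lay below every control pool.

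Some immune and acute phase genes varied more between pools than between groups. Haptoglobin (HP) stood at 8.90 in control pool 4 and between 13.45 and 13.98 in the other control pools, and ranged from 10.65 to 14.26 in the CLA pools. Ceruloplasmin (CP) in control pool 4 differed from the other control pools by -2.28 and -2.03 at 2 of its 3 probe sets, and by -0.39 at the other. The major histocompatibility genes BOLA-N (6.01 to 11.28) and BOLA-DQA5 (4.01 to 8.66), and the interferon-induced ISG12(B) (4.72 to 10.41), ranged widely across the 10 pools. FABP4, a lipid chaperone, stood at 8.39 in CLA pool 4 and between 4.98 and 5.68 in the other pools. At 1 of its 3 probe sets MTSS1 stood at 5.30 in CLA pool 2 and between 8.40 and 9.55 in the other pools, while the other 2 differed there from the other CLA pools by a median of only -0.18.

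With group means removed, the interferon score followed the T and NK lymphocyte score over the 10 pools. Pearson's r was 0.775 (permutation p = 0.0230, Benjamini-Hochberg adjusted 0.0461 over 4 relations) and Spearman's rho 0.830 (permutation p = 0.010), and r was 0.902 without the 2 pools farthest from the median. The cell cycle score did not pass that test against array spread (r = 0.448, permutation p = 0.232; Spearman's rho 0.430, permutation p = 0.242; r = 0.779 without the 2 farthest pools).

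Among 98 families of genes sharing a symbol stem with at least 10 measured members, 1 passed camera with Benjamini-Hochberg adjustment, the proteins of the large mitochondrial ribosomal subunit (MRPL). Of 43 MRPL genes 32 were higher in the CLA pools, with a median of 0.058 (adjusted p = 0.0182), and the adjusted p = 0.975 with an estimated correlation. That median lay at percentile 99.14 of random lists matched on signal. The percentile was taken only for the family past camera, picked from these same arrays, and random genes vary independently. It is therefore no separate support. The family was not set against splits of the arrays or other normalizations. The small subunit family (MRPS) had 18 of 24 genes higher, with a median of 0.044, and did not pass (adjusted p = 0.514).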
